A study of Mus musculus with 12 samples.

How the data were processed

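The study measured nuclear RNA of mouse small-intestine tumours in 12 libraries, 4 each of Apc knockout tumours with Kras WT, Kras G12D and Kras Q61R. Per the labels' protocols, nuclei were isolated from cryopreserved tissue with a 10x Genomics kit and sequenced on an Illumina NovaSeq. The submitters' processing notes name Cell Ranger 7.1.0, Cell Ranger ARC 2.0.2 and the genome build mm10, without saying which tool made which file. The authors deposited UMI counts per gene and barcode for each library, already limited to called barcodes, as whole numbers. The tables hold 52636 genes, of which 52403 IDs are in the GENCODE M21 annotation of mm10 used for coordinates and 233 are not, and 97 symbols belong to more than 1 gene ID.

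Everything after the deposited counts was computed for this re-analysis. Libraries that share more than 50% of their barcodes were joined to a preparation, and UMI counts of a barcode were added over its 2 libraries, which gave 6 preparations and 4340 barcodes. A count table does not show whether the 2 libraries of a preparation read some of the same molecules, so the deeper library alone was used as an alternative. Barcodes with fewer than 200 genes or over 40% mitochondrial UMIs were left out. Doublets were scored per preparation with Scrublet in scanpy 1.11.5 (Python 3.11.15). Its automatic threshold would have removed 91.6% of Kras WT A and 67.7% of Kras WT B, so a score over 0.25 was used in all preparations after this was seen, which removed 17.8% and 10% of Kras WT, 7.64% and 7.81% of Kras G12D, and 11.1% and 2.73% of Kras Q61R barcodes. This left 3881 barcodes with 2571843 to 15831307 UMIs per preparation.

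Kept barcodes were scaled to 10000 UMIs, and 2000 variable genes, 30 principal components, 15 nearest neighbours and Leiden clustering (leidenalg 0.10.2, resolution 1) gave 7 clusters. A cluster was named after a marker list with at least 3 genes at 2-fold or more over the other barcodes. For each marker list with at least 100 UMIs in a preparation, the variance of its UMIs between barcodes beyond counting noise gave an estimated lower bound. It stands for the percent of barcodes with RNA of the list, whether or not a UMI of it was read. Barcodes weigh in by their squared depth, so the bound can exceed the percent of barcodes with a UMI. Shares with UMIs of 4 lists at once have 95% Clopper-Pearson intervals, which cover counting error only.

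The plan fixed before the data were examined took the 12 libraries as replicates and summed UMIs over epithelial clusters. After the shared barcodes and the unnamed clusters were seen, the 6 preparations became the replicates (2 per group) and UMIs of all kept barcodes were summed. The 12 libraries as replicates were kept as an alternative. Tests of cell type shares and within cell types were left out because no cell type but mesothelial cells in 1 preparation reached 20 barcodes, and an exact permutation test of 2 against 2 cannot give a p below 0.333.

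Sums were tested with edgeR 4.0.16 (filterByExpr, TMM, robust dispersions, quasi-likelihood F test, all 3 groups in 1 fit without covariates, R 4.3.3), which left 18490 genes, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Log2 fold changes are edgeR's, and CPM are scaled by TMM. The standard errors (SE) were derived from the test, as the absolute log2 fold change divided by the square root of F. The common dispersion was 0.170. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run beside it. The 35 gene lists and 24 cell type marker lists were fixed before the data were examined, and 5 of their symbols (Ccn1, Ccn2, Ero1a, Myeov, Trop2) were not in the tables. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 35 lists of a comparison, and again with camera's estimated correlation and with fry. Camera at the preset correlation called 14, 21 and 20 lists for Kras G12D against Kras WT, Kras Q61R against Kras WT and Kras Q61R against Kras G12D, the estimated correlation 0 in each, and fry 0, 0 and 1.

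Single genes were named by a rule fixed before the data were examined: past the threshold, at 10 CPM or more in a group, and changed in 1 direction in every fit without 1 library, leaving out numbered gene models. Clone-named loci were treated as such models too, which was decided after they were seen. Fewer than 5 genes passed in each comparison, so the rule's fallback applied, namely the 10 of lowest p that met its other conditions, plus Apc, Kras and up to 4 members of lowest p per list. Further genes named from the cluster and marker lists are members of those lists.

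On data simulated for Kras Q61R against Kras WT with the spread estimated between preparations (17784 genes tested), edgeR recovered 0 of 100 genes changed 2-fold and 12 of 100 changed 4-fold. It called 1 unchanged gene, and the ratios of fitted to true log2 fold changes were 1.02 and 0.983. With a dispersion of 0.01 it recovered 94 and 100 of 100. Camera called a moved list of 20 genes and did not call an unmoved one. Genes were simulated independently of each other, so this does not test camera's calls where members of a list vary together. In 5 sets with no group difference, taking 12 libraries as replicates called 772 to 1044 genes and taking 6 preparations at most 1.

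Alternatives to single choices were normalization (RLE), no filter or a stricter filter on low counts, barcode filters, doublets kept, thinning to equal UMI totals per preparation, only the groups compared, each library or preparation left out, 1 library per preparation, and terms for sex, for the Gm42418 batch (over 8% of UMIs) and for the position score. The replicate number as a block changed 2 choices, since it also took 11 libraries as replicates. The shared-control values came from 20 simulated sets.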

Results

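Single-nucleus RNA was measured with the 10x Genomics platform in small-intestine tumours of mice that lack Apc, a brake on Wnt signalling. The 12 libraries fell into 3 groups of 4, with unmutated Kras (Kras WT), Kras G12D or Kras Q61R. Kras is a membrane-bound switch upstream of the RAF, MEK and ERK kinases, and both amino acid changes keep it in its active state. All 12 libraries carried the Apc knockout per the labels, so no tissue with intact Apc was available for comparison. The libraries held 531 to 911 barcodes each and 596821 to 13311489 unique molecular identifiers (UMIs, counts of single RNA molecules).

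The 12 libraries paired up by their cell barcodes, so that each group held 2 sets of nuclei rather than 4. Kras WT replicates 1 and 2 shared 556 barcodes, which was 99.6% of the smaller library. In the other 5 such pairs, between 98.2% and 99.9% of the smaller library's barcodes were shared, while none of the other 60 pairs of libraries shared more than 1 barcode. UMI totals per shared barcode correlated within the 6 pairs at Pearson r between 0.989 and 0.998 across barcodes, which are not independent replicates. Each pair is called a preparation here, A and B in each group, and the 2 preparations of a group were its replicates (n = 2) in every test. The labels do not say whether preparations came from separate animals. After filtering, the preparations held 461 and 657 barcodes (Kras WT), 762 and 661 (Kras G12D), and 806 and 534 (Kras Q61R). Their UMI totals were 13564867 and 15219284 for Kras WT, 10900727 and 15831307 for Kras G12D, and 5879205 and 2571843 for Kras Q61R. Kras Q61R was therefore measured at lower depth, with a median of 8227 and 4052 UMIs per barcode against 16480 to 28133 in the other 4 preparations.

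**Figure D1:**
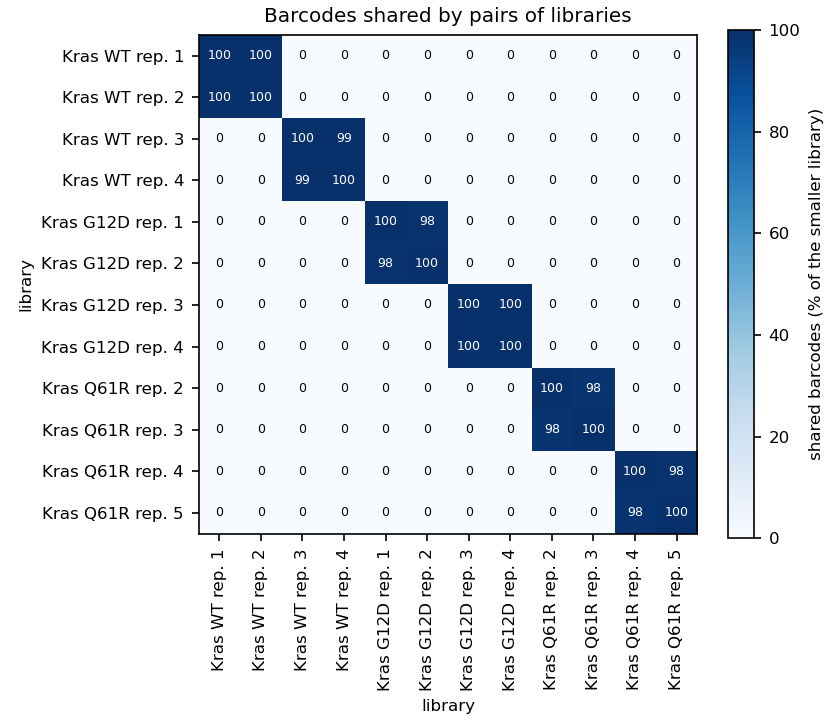
Shared cell barcodes between all pairs of the 12 libraries, as a percent of the smaller library. The 6 bright pairs lie within a genotype at 98.2% to 99.9%, and every other pair is at or below 0.188%.

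Epithelial, immune and stromal transcripts were found together in single barcodes. UMIs of epithelial, B cell, T or NK cell and plasma cell markers occurred jointly in 459 of 461 barcodes of Kras WT preparation A (99.6%, 95% Clopper-Pearson interval 98.4% to 99.9%) and in 92 of 534 of the shallowest preparation, Kras Q61R B (17.2%, interval 14.1% to 20.7%). B cell markers had a median of 86 UMIs per barcode in Kras WT A, where 100% of barcodes held such a UMI. From their even spread, the estimated lower bound on barcodes with their RNA was 98.5% there. It was at least 84.5% in each of the 6 preparations, while 65.2% of Kras Q61R B barcodes held a UMI of the B cell list. Outside Kras WT A these UMIs may come mostly from few members of the list. In Kras Q61R against Kras WT 1 of 8 was higher (median log2 fold change -5.33). The list's sum in Kras Q61R was 344 and 388 CPM, above 229 CPM in Kras WT B. The bound of 84.5% therefore need not show B cell RNA in each preparation. Paneth cell markers, from secretory cells of the crypt base, had a bound of at least 87.2% in every preparation, while 71.0% of Kras Q61R B barcodes held such a UMI. Marker RNA was less evenly spread in Kras Q61R B, where the bound was 18% for macrophage, 20% for fibroblast, 24.2% for smooth muscle and 32.7% for goblet cell markers.

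**Figure D2:**
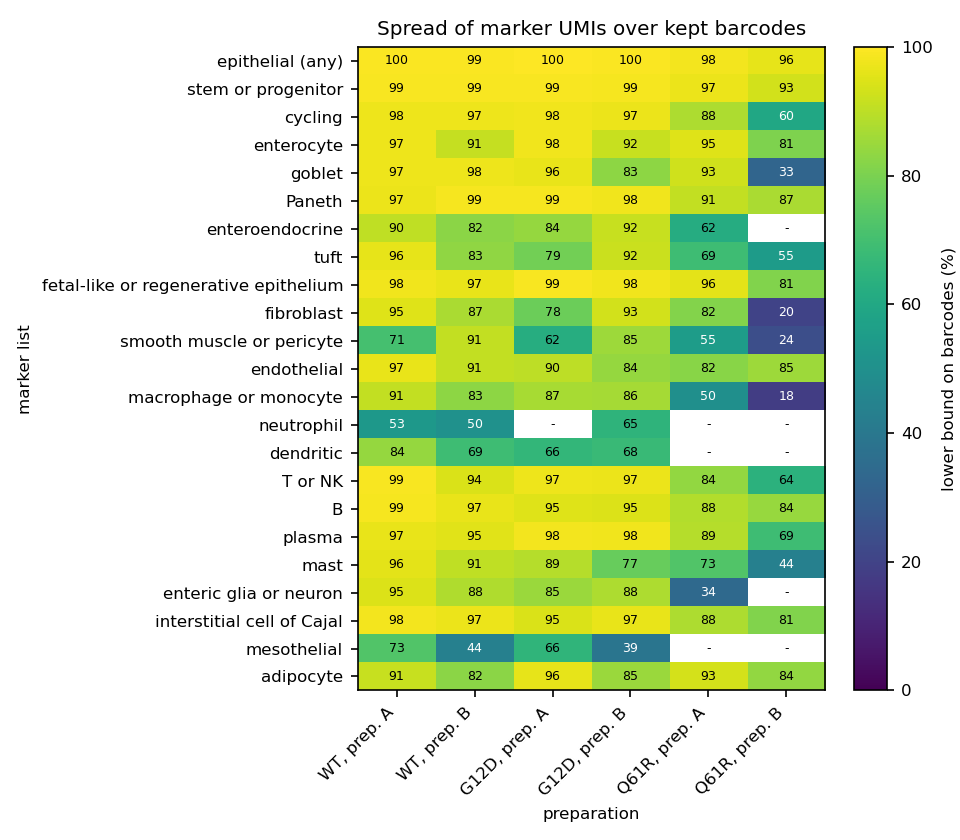
Estimated lower bound on the percent of kept barcodes with RNA of each cell type marker list, in the 6 preparations. It comes from the evenness of the list's UMIs, is weighted by depth, and can exceed the percent of barcodes with a UMI. A dash marks lists with too few UMIs. Most lists lie above 80%, with the lowest bounds for macrophage and fibroblast markers in Kras Q61R preparation B (18% and 20%).

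Clustering separated 2 small groups with marker genes of 1 cell type. A cluster of 47 barcodes carried the mesothelial genes Gpm6a, Muc16, Upk1b and Wt1, and 32 of its barcodes came from Kras WT preparation B. A cluster of 12 barcodes carried 9 smooth muscle or pericyte genes, among them Acta2, Myh11 and Des. The other 5 clusters held no marker gene at 2-fold or more over the rest, so shares of cell types and changes within 1 cell type were not tested. The values below are therefore UMI sums over all kept barcodes of a preparation, in CPM (counts scaled to a common library total), and a higher value can come from more cells of a type or from more RNA per cell.

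Apc and Kras were checked first. Apc (ENSMUSG00000005871, mm10 chromosome 18, 34220924 to 34322552) was at 222 ± 7.45 CPM in Kras WT, 241 ± 2.60 in Kras G12D and 335 ± 19.0 in Kras Q61R (SD, n = 2 preparations each). Its log2 fold change was 0.59 ± 0.17 (SE) for Kras Q61R against Kras WT (edgeR adjusted p = 0.166) and 0.11 ± 0.17 for Kras G12D against Kras WT (adjusted p = 0.976). Kras itself (ENSMUSG00000030265, chromosome 6, 145216699 to 145250239) was at 152 ± 8.08, 174 ± 4.07 and 160 ± 2.29 CPM, with log2 fold changes of 0.19 ± 0.17 and 0.08 ± 0.17 against Kras WT (edgeR adjusted p = 0.966 and 0.831). Across the 12 libraries, Apc ranged from 200 CPM (Kras WT replicate 1) to 350 CPM (Kras Q61R replicate 3), and Kras from 145 CPM (Kras WT replicate 1) to 191 CPM (Kras G12D replicate 3). Counts over whole genes show neither the loss of Apc exons nor which Kras allele a molecule came from, so they do not check the genotype labels.

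The preparations also differed in sex, in where along the intestine their transcripts pointed, and in RNA make-up. Xist, which is expressed from the inactive X chromosome of females, was at 2507 CPM in Kras WT A and 1930 CPM in Kras G12D B and at most 0.850 CPM in the other 4, which expressed Y-linked genes. A position score, the mean log2 CPM of proximal minus distal small-intestine genes, was -2.17 and -1.32 in Kras WT, 0.72 and -1.49 in Kras G12D, and 3.03 and 2.87 in Kras Q61R. Mitochondrial transcripts made up 1.47% and 7.08% of UMIs in Kras WT, 14.1% and 4.44% in Kras G12D, and 7.66% and 5.01% in Kras Q61R. Gm42418, a locus that overlaps ribosomal RNA, took 10.4% to 11% of UMIs in Kras WT B and both Kras Q61R preparations and 3.78% to 5.91% in the other 3. Read as a library batch, this split puts both Kras Q61R preparations on 1 side, so only Kras WT was found in both batches and no comparison could be made within a batch with 2 preparations per group. A fit with a term for this batch takes it from the 2 Kras WT preparations alone. Such a fit compares Kras G12D with Kras WT A only and Kras Q61R with Kras WT B only. It shifts Kras Q61R against Kras G12D by the difference between these 2 preparations.

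The comparison of Kras G12D with Kras WT asks what this mutation adds in tumours without Apc. Tuft cell genes, which mark chemosensory cells, fell together in Kras G12D: 16 of 17 were lower, with a median log2 fold change of -1.19 (camera adjusted p = 1.65e-15, and adjusted p = 0.395 with an estimated correlation). Adjusted over the list alone, 9 of the 17 fell, and over all genes tested 0 did. Among the 9 were Chat, the acetylcholine-producing enzyme (-3.62 ± 0.65, SE, n = 2 preparations per group), the signalling regulator Rgs13 (-2.71 ± 0.51), Sh2d6 (-2.45 ± 0.54) and the taste-pathway channel Trpm5 (-2.91 ± 0.65). The summed level of the list was 460 and 283 CPM in Kras WT and 126 and 288 CPM in Kras G12D, so preparation B was not lower in the sum, in which the abundant kinase gene Dclk1 was at 150 and 94.5 against 24.3 and 157 CPM. Gastric or pyloric genes rose together, with 13 of 16 higher and a median of 1.29 (adjusted p = 4.25e-07, and adjusted p = 0.554 with an estimated correlation). Anxa10, a stomach annexin, was at 9.09 and 2.35 CPM in Kras WT and 49.9 and 32.8 CPM in Kras G12D. Fetal-like and regenerative epithelium genes also rose together (21 of 27 higher, median 0.36, adjusted p = 1.71e-06, and adjusted p = 0.554 with an estimated correlation). Ly6a, which encodes the surface protein Sca-1, rose by 1.90 ± 0.29 when adjusted over the list alone, the only 1 of the 27.

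MAPK pathway activity, EGFR family and cholesterol synthesis genes were higher in Kras G12D as groups, while 2 further lists of ERK-driven genes did not pass. Of 10 MAPK pathway activity genes, 8 were higher (median 0.44, camera adjusted p = 0.000765, and adjusted p = 0.554 with an estimated correlation). The ERK-induced transcription factor Etv4 alone rose when adjusted over the list alone (1.32 ± 0.29). Of the other ERK feedback and target genes 9 of 16 were higher (median 0.17, adjusted p = 0.163), and of the AP-1 and immediate early genes 5 of 17 (median -0.24, adjusted p = 0.165). EGFR family ligands and receptors rose as a group (11 of 14 higher, median 0.38, adjusted p = 0.00471, and adjusted p = 0.638 with an estimated correlation). Egfr was at 131 and 184 CPM in Kras WT and 320 and 256 CPM in Kras G12D. Cholesterol synthesis genes rose together, 19 of 20 being higher (median 0.47, adjusted p = 5.34e-07, and adjusted p = 0.554 with an estimated correlation). Fdft1, which makes squalene, had a log2 fold change of 0.89 ± 0.24 and Hmgcs1 of 0.87 ± 0.27. G2/M cell cycle genes (median 0.25) and NRF2 oxidative stress genes (median 0.09) passed in the same direction (adjusted p = 0.0248 and 0.0334, and adjusted p = 0.784 and 0.554 with an estimated correlation). Mitochondrially encoded genes passed as well (median 1.24, adjusted p = 1.51e-06, and adjusted p = 0.579 with an estimated correlation). Preparation A led this, where they summed to 129436 CPM against 32100 in B. Adjusted over the list alone, 1 of the 13 was called, mt-Nd3 (5.67 ± 1.0).

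Antigen presentation, interferon, Paneth cell, distal intestine and hypoxia genes fell as groups in Kras G12D. All 20 MHC and antigen processing genes were lower (median -1.47, camera adjusted p = 1.42e-09, and adjusted p = 0.562 with an estimated correlation). The MHC class I gene H2-K1 was at 1099 and 826 CPM in Kras WT and 350 and 283 CPM in Kras G12D. B cell markers moved with this list, at 2691 CPM in Kras WT A and 229 to 258 CPM in Kras WT B and the 2 Kras G12D preparations. Mast cell markers also fell (183 and 121 against 53.9 and 44.2 CPM). Macrophage or monocyte markers rose (10 of 12 higher, median 0.73), at 59.6 and 51.7 against 103 and 61.3 CPM in sum. Fibroblast markers rose by member (9 of 13 higher, median 0.33), but their sum was highest in Kras WT B (142 and 359 against 324 and 288 CPM). These 3 had adjusted p = 4.75e-09, 0.000441 and 0.0302, and adjusted p = 0.206, 0.206 and 0.664 with an estimated correlation. Interferon response genes (24 of 25 lower, median -0.75) had adjusted p = 0.000346, and adjusted p = 0.645 with an estimated correlation. Their sum overlapped, at 634 and 350 CPM in Kras WT and 208 and 403 CPM in Kras G12D. Paneth cell genes (17 of 19 lower, median -1.17) had adjusted p = 9.40e-07, and adjusted p = 0.554 with an estimated correlation. In sum they overlapped too (1120 and 3786 against 1540 and 576 CPM). Distal small intestine genes (15 of 17 lower, median -1.06) had adjusted p = 0.00224, and adjusted p = 0.645 with an estimated correlation. Here the sums overlapped as well (2144 and 344 against 654 and 995 CPM). Hypoxia genes (13 of 16 lower, median -0.36) had adjusted p = 0.0248, and adjusted p = 0.554 with an estimated correlation. The other 21 of the 35 lists did not pass the threshold, among them Wnt/beta-catenin targets (median 0.01), crypt base columnar stem cell genes (0.31), goblet cell genes (0.16), and Ras and RAF-MEK-ERK components (0.03). Without Kras WT preparation A, which leaves 1 Kras WT preparation, the MHC, interferon, MAPK activity, mitochondrial, EGFR family, NRF2 and hypoxia lists lost their calls. The G2/M and distal lists lost theirs and turned direction, and enterocyte genes turned direction too. Calls also ended for Paneth, NRF2 and hypoxia genes without Kras WT B (adjusted p = 0.461, 0.306 and 0.214), and for MAPK activity and hypoxia genes without Kras G12D B (adjusted p = 0.149 and 0.382). Without Kras G12D A they ended for interferon, distal, mitochondrial, NRF2 and EGFR family genes (adjusted p = 0.655, 0.332, 0.289, 0.236 and 0.160), and G2/M genes turned direction. With the position score as a term the cholesterol synthesis (adjusted p = 0.0902), MHC (adjusted p = 0.283), EGFR family (adjusted p = 0.565) and NRF2 lists (adjusted p = 0.188) lost their calls, and the G2/M, interferon and mitochondrial lists turned direction. Distal genes are part of that score, so this fit does not test them. Within groups the score differs most between the Kras G12D preparations, which differ in sex and mitochondrial share too. The losses and turns with it therefore do not point to position.

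No single gene passed for Kras G12D against Kras WT among 18490 tested with edgeR's quasi-likelihood test (lowest adjusted p = 0.586). At an unadjusted p below 0.05 there were 840 genes, 366 of them higher, where chance alone gives 924. This number was 1683 without Kras WT A, 1710 without Kras WT B, 1600 with the Gm42418 batch and 1298 with sex as a term. The batch fit compares Kras G12D with Kras WT A alone, so it is no separate check beside the fit without Kras WT B. DESeq2 called 59 genes on the same sums as the main fit and limma-voom 0. The genes of lowest p, none of which passed by edgeR, are given as values. Syt16 (ENSMUSG00000044912, chromosome 12, 73997661 to 74273267), a member of the synaptotagmin family of vesicle proteins, was at 28.1 ± 5.58 CPM in Kras G12D and 3.45 ± 0.122 in Kras WT (log2 fold change 3.02 ± 0.35). Tc2n (1.83 ± 0.22), the actin-nucleating formin Fmnl2 (1.57 ± 0.23), the matrix metalloproteinase Mmp28 (1.89 ± 0.25), Ly6a (1.90 ± 0.29) and the adhesion protein Alcam (1.30 ± 0.21) were also higher in both Kras G12D preparations than in either Kras WT preparation. Lower in both were the diacylglycerol kinase Dgki (-2.34 ± 0.26), the homeobox gene Pitx1 (-2.24 ± 0.27), Ccdc129 (-3.34 ± 0.46) and the phospholipase Pla2g4c (-5.07 ± 0.70).

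The comparison of Kras Q61R with Kras WT asks the same of the second mutation. Paneth cell genes fell together, with 17 of 19 lower and a median log2 fold change of -3.65 (camera adjusted p = 5.28e-14, and adjusted p = 0.345 with an estimated correlation). Adjusted over the list alone 15 of the 19 fell, and over all genes tested 0 did. The pentraxin Mptx2 had a log2 fold change of -5.92 ± 0.64 (SE, n = 2 preparations per group) and the lectin Itln1 of -4.43 ± 0.78. Itln1 was at 213 and 582 CPM in Kras WT and 15.6 and 21.7 CPM in Kras Q61R. Defensin genes such as Defa22 (-5.76 ± 0.69) went the same way, though reads of near-identical defensin copies can be assigned to the wrong one. Gastric or pyloric genes rose together (13 of 16 higher, median 2.47, adjusted p = 4.90e-08, and adjusted p = 0.345 with an estimated correlation). Of them 6 rose when adjusted over the list alone, including Anxa10 (4.56 ± 0.76), the pepsinogen gene Pgc (4.16 ± 0.60), Psca (3.73 ± 0.77) and the transcription factor Onecut2 (1.45 ± 0.28). Fetal-like and regenerative epithelium genes rose together (22 of 27 higher, median 0.82, adjusted p = 2.80e-06, and adjusted p = 0.345 with an estimated correlation). Adjusted over the list alone 10 rose and 1 fell, with Ly6a (2.15 ± 0.29), S100a6 (1.58 ± 0.23) and the annexin Anxa3 (2.68 ± 0.43) among those up.

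Hypoxia genes and genes of the proximal small intestine rose in Kras Q61R. Of 16 hypoxia genes 13 were higher (median 0.59, camera adjusted p = 9.33e-05, and adjusted p = 0.345 with an estimated correlation). Of these 8 rose when adjusted over the list alone, among them Higd1a (1.40 ± 0.28), Ndrg1 (1.81 ± 0.39) and the vasodilator peptide gene Adm (2.27 ± 0.53). Proximal small intestine genes rose together (12 of 16 higher, median 1.92, adjusted p = 1.36e-06, and adjusted p = 0.345 with an estimated correlation). Adjusted over the list alone 5 rose and 1 fell. Of the duodenal iron genes, the exporter Slc40a1 was at 8.71 and 7.53 CPM in Kras WT and 83.1 and 98.3 CPM in Kras Q61R, and the reductase Cybrd1 at 4.10 and 11.4 against 801 and 494 CPM. Distal small intestine genes fell together (14 of 17 lower, adjusted p = 2.59e-05, and adjusted p = 0.471 with an estimated correlation). Their sum overlapped, at 894 and 300 CPM in Kras Q61R and 2144 and 344 CPM in Kras WT. Of the distal genes 2 fell when adjusted over the list alone, including the ileal bile acid transporter Slc10a2 (-4.13 ± 0.75). EGFR family ligands and receptors rose as a group (median 0.57, adjusted p = 0.0139, and adjusted p = 0.519 with an estimated correlation). Its members Erbb3 (1.63 ± 0.28), the ligand gene Btc (1.93 ± 0.37) and the feedback inhibitor Errfi1 (1.63 ± 0.36) rose when adjusted over the list alone. NRF2 oxidative stress genes rose as a group (median 0.33, adjusted p = 0.0202, and adjusted p = 0.345 with an estimated correlation). There 2 rose when adjusted over the list alone, Gsta4 (3.04 ± 0.37) and Gsta3 (3.69 ± 0.54), which belong to a family of similar glutathione transferases. Enterocyte absorptive (median 0.46), senescence and p53 target (0.62) and mitochondrially encoded genes (0.34) also passed (adjusted p = 0.0205, 0.0343 and 0.0226, and adjusted p = 0.635, 0.471 and 0.626 with an estimated correlation).

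Immune, goblet cell, tuft cell and cell cycle genes fell in Kras Q61R. Of 20 MHC and antigen processing genes 19 were lower (median -2.66, camera adjusted p = 5.33e-11, and adjusted p = 0.471 with an estimated correlation). Of these 15 fell when adjusted over the list alone, such as the class I gene H2-D1 (-2.31 ± 0.37) and the class II genes Cd74 (-5.52 ± 1.08) and Ciita (-3.49 ± 0.80). B cell markers were at 344 and 388 CPM in Kras Q61R against 2691 and 229 CPM in Kras WT, and Cd74 at 2.93 and 2.93 CPM against 224 and 46.2 CPM. T or NK cell markers (227 and 160 against 1086 and 306 CPM), plasma cell markers (299 and 162 against 812 and 363 CPM) and dendritic cell markers (11.5 and 9.20 against 41.1 and 20.2 CPM) fell beside them, as did mast cell markers (46.6 and 57.7 against 183 and 121 CPM), with adjusted p = 0.0126, 0.0115, 0.0131 and 0.0108, and adjusted p = 0.834, 0.758, 0.495 and 0.495 with an estimated correlation. Interferon response genes (median -2.15, 1 down over the list alone, Stat1, -3.07 ± 0.59) and NF-kB and inflammatory genes (median -1.68, 4 down, among them the oxidase genes Duox2, -5.69 ± 0.98, and Duoxa2, -5.86 ± 0.74) fell together (adjusted p = 1.26e-08 and 0.000271, and adjusted p = 0.471 for both with an estimated correlation). Goblet cell genes (17 of 19 lower, median -1.20) and tuft cell genes (15 of 17 lower, median -1.60) fell together (adjusted p = 6.89e-06 and 2.59e-05, and adjusted p = 0.458 and 0.345 with an estimated correlation). In these lists 7 and 3 members fell when adjusted over the list alone, including the secretory regulator Atoh1 (-2.31 ± 0.47) and the tuft cell gene Kctd12 (-2.68 ± 0.41). Of 27 G2/M genes 26 were lower (median -0.84) and of 26 G1/S genes 24 (median -0.82), and both lists fell (adjusted p = 0.000123 and 0.000971, and adjusted p = 0.586 for both with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, instead rose when adjusted over the list alone (2.31 ± 0.38). Notch pathway (median -1.18), BMP response (-1.11) and Wnt/beta-catenin target genes (-0.70) fell (adjusted p = 0.0147, 0.0161 and 0.00241, and adjusted p = 0.345, 0.471 and 0.550 with an estimated correlation). The sum of the Wnt list overlapped between groups, at 3960 and 4597 CPM in Kras Q61R and 3731 and 7648 CPM in Kras WT, while the Notch and BMP sums did not. Of the Notch list 7 fell and 1 rose when adjusted over the list alone, for example Hes1 (-1.64 ± 0.33). Of the Wnt list 1 fell, the Wnt modulator Dkk2 (-5.16 ± 0.94), at 248 and 454 CPM in Kras WT and 12.1 and 7.11 CPM in Kras Q61R.

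MAPK pathway activity genes as a group did not pass in Kras Q61R (median 0.24, camera adjusted p = 0.25, and adjusted p = 0.635 with an estimated correlation), although Etv4 rose when adjusted over the list alone (1.58 ± 0.29). Other lists not past the threshold were other ERK feedback and target genes (median 0.11), AP-1 and immediate early genes (-0.29), Ras and RAF-MEK-ERK components (0.04), crypt base columnar stem cell genes (-0.37), YAP/TEAD targets (-0.01), TGF-beta response genes (-0.41), epithelial-mesenchymal transition genes (-0.97), enteroendocrine cell genes (-0.41), glycolysis genes (0.25), cholesterol synthesis genes (0.26), colon genes (-0.94), stress and dissociation genes (-0.46) and sex-linked genes (0.77). With the position score as a term 12 lists passed, not all of them among the 21. Sex-linked genes were newly called, and interferon, NF-kB and mitochondrial genes passed in the opposite direction. The MHC, goblet, EGFR family, Wnt and BMP lists also turned direction with this term. Hypoxia (adjusted p = 0.357), NRF2 (adjusted p = 0.342), tuft cell (adjusted p = 0.0796), Notch (adjusted p = 0.0688) and enterocyte genes (adjusted p = 0.974) lost their calls with it. The score nearly follows the Kras Q61R group, so that fit has little power and its lost calls do not point to position. Without Kras WT preparation B the G2/M (adjusted p = 0.204), G1/S (adjusted p = 0.115), Wnt (adjusted p = 0.656), BMP, NRF2 and senescence lists lost their calls and enterocyte genes turned direction. The EGFR family and mitochondrial lists lost theirs without Kras WT A (adjusted p = 0.292 and 0.842), enterocyte, BMP and mitochondrial genes without Kras Q61R A (adjusted p = 0.881, 0.0727 and 0.0905), and senescence genes without Kras Q61R B (adjusted p = 0.133).

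No single gene passed for Kras Q61R against Kras WT in edgeR's test (0 of 18490, lowest adjusted p = 0.0590). At an unadjusted p below 0.05 there were 3772, of which 1786 were higher, against 924 by chance. Without Kras Q61R A or B this number was 1781 or 2049. DESeq2 called 1489 genes and limma-voom 0, with 2789 at an unadjusted p below 0.05. The 10 genes of lowest p did not pass in edgeR. Syt16 was at 134 ± 50.2 CPM in Kras Q61R (log2 fold change 5.28 ± 0.38), Tc2n at 386 ± 76.2 against 53.1 ± 5.73 CPM (2.86 ± 0.23), and Fmnl2 at 1282 ± 118 against 209 ± 5.52 CPM (2.62 ± 0.23), and these 3 were also among the genes of lowest p for Kras G12D. The other higher ones were the retinoic acid-degrading enzyme Cyp26b1 (4.02 ± 0.36), the phosphatase Ptprr, which acts on ERK (3.47 ± 0.37), and Atg9b (3.35 ± 0.36). Lower were Pitx1 (-2.96 ± 0.29), Atp2a3, a calcium pump (-2.91 ± 0.26), Dnah8 (-2.56 ± 0.23) and the kinase gene Dmpk (-3.04 ± 0.30). Without Kras WT B 124 genes were called, without Kras G12D A 87 and without Kras G12D B 83, and with sex as a term 43.

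The comparison of Kras Q61R with Kras G12D asks whether the mutations differ. Hypoxia genes rose in Kras Q61R relative to Kras G12D: all 16 were higher, with a median log2 fold change of 0.90 (camera adjusted p = 5.08e-12, and adjusted p = 0.152 with an estimated correlation). Fry, a rotation test, also called them (adjusted p = 0.0213). Adjusted over the list alone 8 of the 16 rose, and over all genes tested 0 did. They included Adm (3.49 ± 0.56, SE, n = 2 preparations per group), Ankrd37 (2.48 ± 0.49), Ndrg1 (1.85 ± 0.39) and Ero1l, an oxidase of protein folding (1.12 ± 0.24). Ndrg1 was at 275 and 179 CPM in Kras Q61R, 84.9 and 41.4 in Kras G12D, and 66.0 and 63.4 in Kras WT. Cell cycle genes were lower: all 27 G2/M genes (median -1.03) and 25 of 26 G1/S genes (median -0.94), and both lists fell (adjusted p = 1.24e-11 and 8.46e-08, and adjusted p = 0.470 for both with an estimated correlation). None of these cell cycle genes passed when adjusted over the list alone, and the mitotic checkpoint kinase gene Bub1b was at 14.4 and 11.7 CPM in Kras Q61R against 36.9 and 28.3 CPM in Kras G12D.

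Paneth and goblet cell genes were lower, and enterocyte absorptive and proximal genes higher, in Kras Q61R than in Kras G12D. Paneth cell genes (median -2.45, 5 down over the list alone, such as Mptx2, -4.41 ± 0.64) and goblet cell genes (median -1.34, 6 down, such as the transcription factors Foxa3, -1.41 ± 0.29, and Atoh1, -2.22 ± 0.47) fell together (camera adjusted p = 1.21e-12 and 8.01e-09, and adjusted p = 0.470 for both with an estimated correlation). Proximal small intestine genes (median 1.99, 2 up over the list alone, Cybrd1, 4.84 ± 1.0, and Slc40a1, 2.40 ± 0.52) and enterocyte absorptive genes (26 of 29 higher, median 1.58, 0 over the list alone) rose together (adjusted p = 5.47e-08 and 2.10e-06, and adjusted p = 0.470 and 0.515 with an estimated correlation). The fructose and glucose transporter genes Slc2a5 and Slc2a2 were at 24.0 and 9.62 and at 109 and 20.5 CPM in the 2 Kras Q61R preparations, against 4.0 and 1.99 and 5.62 and 0.342 CPM in Kras G12D. Gastric or pyloric (median 0.42), fetal-like (0.34) and glycolysis genes (0.28) also rose (adjusted p = 0.00108, 0.0164 and 0.0307, and adjusted p = 0.470 for each with an estimated correlation). Interferon response (median -1.47), MHC and antigen processing (-1.42) and NF-kB genes (-0.87) fell (adjusted p = 7.88e-07, 5.40e-06 and 0.00109, and adjusted p = 0.470 for each with an estimated correlation). T or NK and plasma cell markers moved with them, T or NK markers at 227 and 160 CPM in Kras Q61R against 366 and 612 in Kras G12D, and plasma cell markers at 299 and 162 against 923 and 2777 CPM. Macrophage or monocyte markers were lower too (10 of 12, median -0.84, adjusted p = 0.00622, and adjusted p = 0.566 with an estimated correlation), at 58.9 and 63.6 against 103 and 61.3 CPM in sum.

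Wnt/beta-catenin targets (20 of 22 lower, median -0.71), BMP response genes (-0.98), crypt base columnar stem cell genes (-0.36), Notch pathway genes (-0.67), distal small intestine genes (13 of 17 lower), colon genes (-0.44) and cholesterol synthesis genes (-0.31) were the other lists that fell in Kras Q61R relative to Kras G12D. Their camera adjusted p ranged from 0.000329 (Wnt) to 0.0498 (Notch and cholesterol), and all had an adjusted p of 0.470 with an estimated correlation except cholesterol synthesis (adjusted p = 0.690). Fibroblast markers fell in the same comparison (11 of 13 lower, median -1.04, adjusted p = 0.00328, and adjusted p = 0.566 with an estimated correlation), at 139 and 230 against 324 and 288 CPM. Dkk2 (-5.54 ± 0.96), the stem cell genes Aqp4 (-2.25 ± 0.44) and Clca3b (-2.61 ± 0.52), Slc10a2 (-3.72 ± 0.74) and Satb2, a colonic transcription factor (-2.82 ± 0.40), fell when adjusted over the list alone. MAPK pathway activity genes (median -0.24), tuft cell genes (-0.02), enteroendocrine cell genes (-0.65) and the other 12 of 35 lists did not pass. Without Kras G12D A 14 lists passed instead of 20, and the cholesterol (adjusted p = 0.842), gastric (adjusted p = 0.504), Notch (adjusted p = 0.274), stem cell (adjusted p = 0.111), fetal-like and glycolysis lists (both adjusted p = 0.0860) lost their calls. Calls ended without Kras Q61R A for stem cell, glycolysis, enterocyte and Notch genes (adjusted p = 0.211, 0.111, 0.103 and 0.0511), and without Kras Q61R B for cholesterol, fetal-like, colon and Notch genes (adjusted p = 0.714, 0.682, 0.209 and 0.152). NF-kB genes lost theirs without Kras G12D B (adjusted p = 0.25), and colon genes without either Kras WT preparation (adjusted p = 0.0731 and 0.0842). With the Gm42418 batch as a term 14 passed, and the MHC and distal lists turned direction. The calls of interferon (adjusted p = 0.897), glycolysis (adjusted p = 0.961), NF-kB, fetal-like, Notch, cholesterol and colon genes ended with this term. With the position score as a term the calls ended for Wnt (adjusted p = 0.994), BMP (adjusted p = 0.803), enterocyte (adjusted p = 0.211), fetal-like (adjusted p = 0.103), Notch, glycolysis and colon genes. The goblet, interferon, MHC and NF-kB lists turned direction with it. Within groups the score differs most between the Kras G12D preparations, which differ in sex and mitochondrial share too. These losses and turns therefore do not point to position.

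No single gene passed between the mutants in edgeR's test (0 of 18490, lowest adjusted p = 0.358), with 2000 at an unadjusted p below 0.05 (993 higher in Kras Q61R) against 924 by chance. DESeq2 called 297 and limma-voom 0 (1463 at an unadjusted p below 0.05). Of the genes of lowest p, none passing in edgeR, higher in Kras Q61R were the stomach proton pump gene Atp4a (5.08 ± 0.59), the iron importer Slc11a2 (3.90 ± 0.51), Cyp26b1 (3.03 ± 0.34), Cyp2c66 (4.56 ± 0.62), the nuclear receptor Rorc (2.29 ± 0.32) and Selenbp1 (3.18 ± 0.45). Atp4a was at 28.4 ± 11.7 CPM in Kras Q61R and 0.807 ± 0.468 CPM in Kras G12D, and Slc11a2 at 433 ± 266 and 29.0 ± 8.81 CPM. Lower were Dnah8 (-2.06 ± 0.23), Lypd8, which binds gut bacteria (-1.61 ± 0.18), Satb2 and the defensin Defa29 (-3.76 ± 0.45). Without Kras G12D A 14 genes were called.

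**Figure D3:**
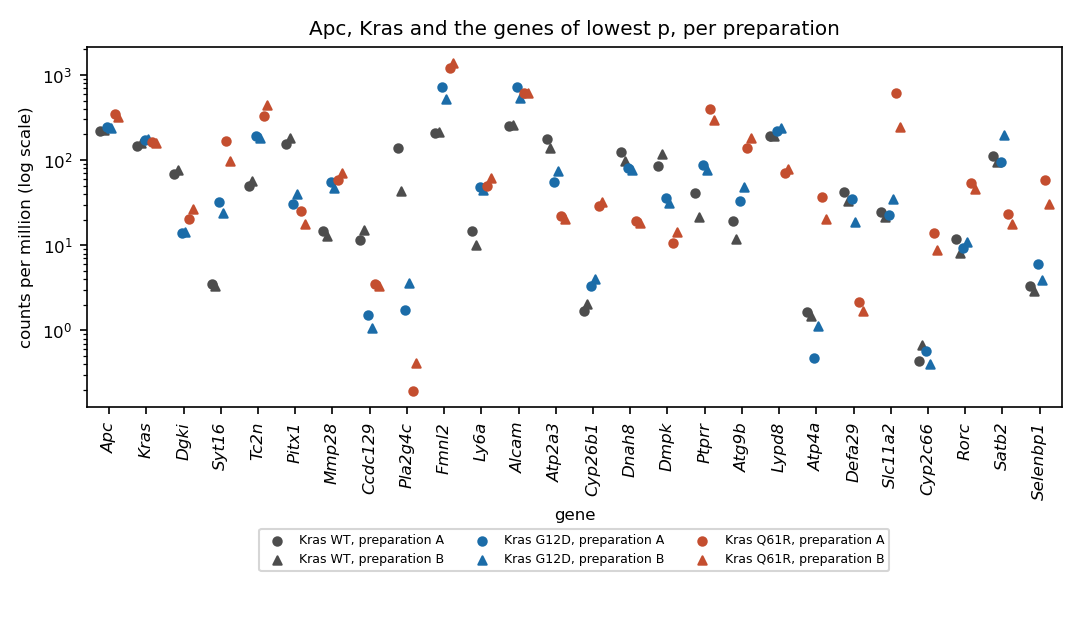
CPM (log axis) of Apc, Kras and the genes of lowest p in the 3 comparisons, with 1 point per preparation, coloured by Kras group. Syt16, Tc2n and Fmnl2 lie lowest in Kras WT and highest in Kras Q61R, with Fmnl2 at 209, 623 and 1282 CPM on average, while Kras lies near 160 CPM in all groups.

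Effects of the Kras mutations on single genes were compared across all 18490 tested genes, which are not independent replicates. No gene was called by edgeR in both comparisons with Kras WT, in which 840 and 3772 genes had an unadjusted p below 0.05, and DESeq2 called 59 and 1489. Their log2 fold changes correlated at Pearson r = 0.556, with a covariance of 0.596. Simulated unchanged groups gave r = 0.431 (0.410 to 0.449 over 20 sets) and a covariance of 0.253, since both comparisons share their controls. Genes were simulated independently of each other, while members of some lists vary together in the data. For Kras Q61R against Kras WT, camera's estimated correlation ran from -0.0577 (sex-linked genes) to 0.888 (enterocyte absorptive genes). The simulated range may therefore be too narrow, and r = 0.556 above it does not show an effect shared by the mutants. On another measure, means of log2(CPM + 0.5), r was 0.635 with shared controls and 0.467 in the simulated sets. With 1 Kras WT preparation as control of each mutant, r on this measure was 0.163 with A for Kras G12D and B for Kras Q61R, and 0.0626 the other way round.

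**Figure D4:**
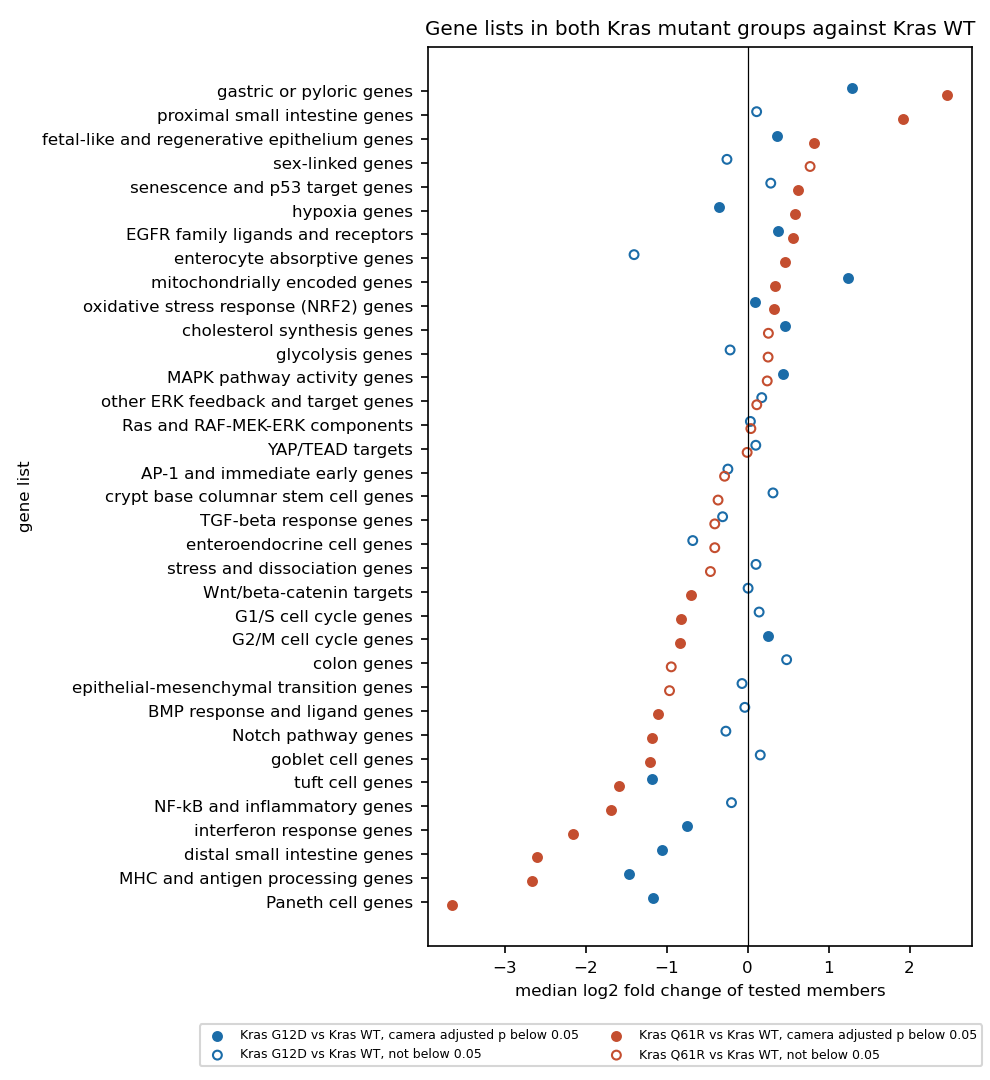
Median log2 fold change of the tested members of 35 gene lists in Kras G12D (blue) and Kras Q61R (red) against Kras WT, with filled points for camera adjusted p below 0.05 at a preset correlation of 0.01. Gastric or pyloric genes lie at 1.29 and 2.47 and Paneth cell genes at -1.17 and -3.65, and none of the filled points kept its call with an estimated correlation.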

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

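Of the tests in this part, the bound on barcodes with B cell markers was chosen after the result was seen, and how to read the split counts was settled only after they were known.

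Shared barcodes were raised because they lie in data outside the main measurement and far above the 0.188% that was the most any other pair of libraries shared. They made up 99.6% of the smaller library for Kras WT replicates 1 and 2, 99.4% for Kras WT 3 and 4, 98.5% for Kras G12D 1 and 2, 99.9% for Kras G12D 3 and 4, 98.2% for Kras Q61R 2 and 3, and 98.5% for Kras Q61R 4 and 5. Kras was at 170.906 CPM over all deposited barcodes of Kras Q61R replicate 4, far from 139 to 144 CPM in the other 3 libraries of its group, and this was 1 of 21 sets of library values examined, of which chance puts about 1 in 20 apart. That library was the shallowest, with 102 Kras UMIs.

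Taken as 12 separate replicates, the libraries gave 296, 4488 and 1830 called genes for Kras G12D against Kras WT, Kras Q61R against Kras WT and Kras Q61R against Kras G12D, where the 6 preparations gave 0 by edgeR with 840, 3772 and 2000 genes at an unadjusted p below 0.05 (DESeq2 59, 1489 and 297, limma-voom 0 in each). Counting the same nuclei more than once is the technical explanation, and the Kras genotype the biological one. With the 8 Kras WT and Kras Q61R libraries, the genotype split called 3988 genes and the splits that mix genotypes 134 and 0. The bound written beforehand would have set double counting aside at 134, but it was wrong, because a mixed split turns the genotype difference into spread within its groups, and because simulated sets with no difference gave 772 to 1044 calls from 12 libraries. How many of the calls come from double counting therefore cannot be told apart from the genotype, and 2 preparations per group make too few splits to weigh chance.

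Barcodes did not separate into cell types. In Kras WT preparation A the estimated lower bound for B cell markers was 98.5% of barcodes, and 100% held a UMI of them. RNA of many cells in each barcode may be the source, since a test that put B cell RNA in a minority of barcodes would have given a low bound. Such RNA could come from free RNA in the droplets or from clumps of nuclei, which were not tested apart. No biological explanation was tested, as no group of the design calls for one.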

How the results depend on the processing

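Chosen after the data were seen were the fits with 12 libraries as replicates, with only the deeper or shallower library of a preparation, with a term for sex, Gm42418 batch or position score, without mitochondrial and rRNA-overlapping loci, without the stromal clusters, with barcodes in both libraries only, and without each preparation, while all others were planned.

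Counts of genes called, 0 in each comparison, are given here in the order Kras G12D against Kras WT, Kras Q61R against Kras WT, and Kras Q61R against Kras G12D. They were 45, 1240 and 224 without a filter on low counts, 59, 1489 and 297 with DESeq2, and 296, 4488 and 1830 with 12 libraries as replicates. Only the shallower library of each preparation gave 0, 9 and 0. Sex as a term gave 0, 43 and 2, the Gm42418 batch 0, 1 and 1, and the position score 1, 1 and 0. Leaving out a library or preparation gave 0 to 1, 0 to 124 (without Kras WT B) and 0 to 14 (without Kras G12D A). All other alternatives but the pairing block gave 0. Genes at an unadjusted p below 0.05 against Kras WT, 840 for Kras G12D and 3772 for Kras Q61R, were 570 to 1710 and 1781 to 3974 without a library or preparation, 1298 and 3677 with sex, and 1600 and 3664 with the batch as a term. The 30 genes named for low p all passed with DESeq2 and with 12 libraries, and 28 did without the filter. Apc reached adjusted p = 0.00220 for Kras Q61R against Kras WT and adjusted p = 0.0225 against Kras G12D with 12 libraries, where the log2 fold changes were 0.58 and 0.43, and Kras was not called by any alternative.

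The replicate numbers as a pairing block gave 79, 2512 and 960 genes and 15, 21 and 17 lists, with 11 libraries as replicates, so block and replicate unit changed together. Residuals of libraries with the same number correlated at -0.350 to 0.126, so the numbers do not mark pairs. With the block, Apc had adjusted p = 0.0224 for Kras Q61R against Kras WT.

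Lists past the threshold (14, 21 and 20) fell to 0 in each comparison with an estimated correlation, and to 0, 0 and 1 with fry. The position score left 11, 12 and 15. Leaving out a library or preparation left 9 (without Kras WT A) to 18 for Kras G12D against Kras WT, 17 to 23 for Kras Q61R against Kras WT, and 14 to 21 for Kras Q61R against Kras G12D.

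Some lists turned direction, given here with camera's unadjusted value. For Kras G12D against Kras WT these were Wnt targets with the batch term (0.00674), and with the position score goblet (0.00156), G2/M (0.0249), interferon (0.301), NF-kB (0.000871), distal (0.328) and mitochondrial genes (0.581). For Kras Q61R against Kras WT they were mitochondrial genes with the batch term (0.673), and with the position score EGFR family (0.284), Wnt (0.610), goblet (0.0448), BMP (0.738), interferon (0.0163), MHC (0.204), NF-kB (0.00188), distal (0.0617), sex-linked (3.19e-06) and mitochondrial genes (1.83e-09). For Kras Q61R against Kras G12D they were MHC (0.0524) and distal genes (0.127) with the batch term, and with the position score AP-1 (0.00629), goblet (0.343), interferon (0.00520), MHC (0.00632), NF-kB (0.00135), distal (0.0305) and sex-linked genes (1.99e-07). The score is made from the proximal and distal lists, so the turns of the distal list with it are built in.

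Lists that lost their call without turning direction are given with their adjusted p. With the position score these were EGFR family (adjusted p = 0.565), MHC (0.283), cholesterol (0.0902) and NRF2 genes (0.188) for Kras G12D against Kras WT. They were enterocyte (0.974), hypoxia (0.357), NRF2 (0.342), tuft (0.0796) and Notch genes (0.0688) for Kras Q61R against Kras WT. For Kras Q61R against Kras G12D they were Wnt (0.994), BMP (0.803), glycolysis (0.798), colon (0.225), enterocyte (0.211), fetal-like (0.103) and Notch genes (0.0719). The stricter count filter gave 14, 15 and 20 lists, newly called ones included. It ended the calls of NRF2 and distal genes (both 0.139) for Kras G12D against Kras WT, of senescence (0.163), enterocyte (0.136), NRF2 (0.0789), BMP (0.0581), NF-kB and mitochondrial genes (both 0.0534) for Kras Q61R against Kras WT, and of gastric and NF-kB genes (both 0.114) between the mutants. The batch term ended those of Paneth (0.424), NRF2 (0.367) and hypoxia genes (0.186) for Kras G12D, of the EGFR family (0.336) for Kras Q61R, and of interferon, NF-kB, fetal-like, Notch, glycolysis, cholesterol and colon genes (0.0835 to 0.961) between the mutants. Sex as a term ended those of EGFR family (0.0850) and mitochondrial genes (0.945) for Kras Q61R, and of NF-kB, glycolysis, distal and colon genes (0.0756 to 0.123) between the mutants. Apart from fits without a library or preparation, with an estimated correlation or with fry, the remaining fits ended calls of NRF2 and hypoxia genes for Kras G12D, Notch, senescence, NRF2, enterocyte and mitochondrial genes for Kras Q61R, and fetal-like, stem cell, Notch, glycolysis, cholesterol and colon genes between the mutants.

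Other lists turned direction in a fit without 1 library or preparation, and the same value then ranged over all such fits as follows. For Kras G12D against Kras WT it was 9.09e-15 to 0.347 for enterocyte, 6.21e-07 to 0.414 for G2/M, 2.33e-09 to 0.469 for distal, 4.71e-05 to 0.859 for Wnt, and 0.00503 to 0.977 for goblet genes. For Kras Q61R against Kras WT it was 9.57e-09 to 0.722 for mitochondrial and 9.65e-12 to 0.881 for enterocyte genes.

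Tuft cell, gastric and fetal-like genes for Kras G12D against Kras WT, Paneth cell, gastric, proximal and fetal-like genes for Kras Q61R against Kras WT, and hypoxia genes for Kras Q61R against Kras G12D kept their calls in all fits but those with an estimated correlation or fry, and hypoxia genes with fry too (for proximal genes the fit with the position score is no test). The correlation of both mutants' effects, 0.556, was 0.163 and 0.0626 with separate Kras WT preparations as controls, and 0.546 to 0.588 in the other fits. Planned fits with Leiden resolutions of 0.5 and 2, with cell type shares and within cell types were not made, because clusters had no cell type. The cause of these changes was not tested.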

Other observations

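Of the tests in this part, those with sex or batch as a term and the comparison of genes with and without thinning were chosen after the result was seen. The marker lists of cell types gave further differences between the groups. Mast cell markers fell in Kras G12D against Kras WT (6 of 7 lower, median log2 fold change -3.40, camera adjusted p = 4.75e-09, and adjusted p = 0.206 with an estimated correlation), with 4 down when adjusted over the list alone. The mast cell protease gene Mcpt1 was at 57.5 and 22.3 CPM in Kras WT, 1.72 and 4.21 CPM in Kras G12D, and 4.68 and 6.27 CPM in Kras Q61R. Macrophage or monocyte markers rose in Kras G12D (10 of 12 higher, median 0.73, camera adjusted p = 0.000441, and adjusted p = 0.206 with an estimated correlation), 0 of them when adjusted over the list alone. Preparation A led their sum, at 103 CPM against 61.3 in B and 59.6 and 51.7 in Kras WT. Plasma cell markers fell in Kras Q61R against Kras G12D (7 of 8 lower, median -2.85, adjusted p = 1.62e-06, and adjusted p = 0.566 with an estimated correlation), with 4 down when adjusted over the list alone. Pparg, a lipid-sensing nuclear receptor held by the adipocyte list and also expressed by gut epithelium, was at 50.7 and 88.2 CPM in Kras WT, 188 and 101 in Kras G12D, and 643 and 591 in Kras Q61R, and was the only 1 of 3 tested adipocyte genes called over the list alone in Kras Q61R against Kras WT. Exocrine pancreas markers summed to 6.27 CPM in Kras Q61R B and at most 0.471 CPM in the other 5 preparations.

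Some signalling genes changed in Kras Q61R against Kras WT within lists that did not pass as a whole. Of 15 TGF-beta response genes 1 rose and 4 fell when adjusted over the list alone, the receptor gene Tgfbr2 (0.85 ± 0.23, SE, n = 2 preparations per group) up and the feedback genes Skil (-1.28 ± 0.27) and Smad7 (-1.36 ± 0.37) among those down. Of 21 YAP/TEAD targets 3 rose, Myof (1.31 ± 0.27), Asap1 (1.11 ± 0.26) and Igfbp3 (1.70 ± 0.41), and of 20 crypt base columnar stem cell genes 3 fell, among them Slc14a1 (-2.45 ± 0.44) and Olfm4 (-3.46 ± 0.89). The heat shock gene Hsph1 fell in the stress list (-2.22 ± 0.43). All of these calls are adjusted over the list alone, and over all genes tested edgeR called 0 (3772 at an unadjusted p below 0.05, DESeq2 1489, limma-voom 0).

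The difference between Kras Q61R and Kras WT was larger than that between Kras G12D and Kras WT, with 3772 against 840 genes at an unadjusted p below 0.05 (1781 to 3974 against 570 to 1710 in fits without a library or preparation), and Kras Q61R stood apart in its position score. With every preparation thinned to the shallowest UMI total, 2953 of 13813 tested genes had an unadjusted p below 0.05, where chance gives 691. Of these 2586 were among the 3772 and in the same direction, which argues against lower UMI totals as the whole cause. The batch term compares Kras Q61R with Kras WT B alone. There were 3677 genes with sex and 3664 with the Gm42418 batch as a term, which argues against either as the whole cause of the difference. Position along the intestine may account for part of it: the difference correlated at r = 0.387 across genes with that between the Kras G12D preparations, and 70.5% of the 3772 genes went the same way in both, between the bounds set beforehand for position as the whole cause, with a slope of 0.158 where the position scores have a ratio of 0.470. Those 2 preparations differ in sex and mitochondrial share too, so neither value is specific to position. A part from sex or library batch stays open (r = 0.151 with the difference between the Kras WT preparations, between the bounds set beforehand). Kras WT B matched both Kras Q61R preparations in sex and batch, while Kras WT A differed in both. The Kras Q61R genotype stays open too, because both Kras Q61R preparations had the highest position scores. No label gives their position, and the score is made from the same transcripts, so genotype and position cannot be told apart.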
